A study of Homo sapiens with 11 samples.

How the data were processed

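Gene expression was measured on 11 microarrays with 2 channels of an established human glioblastoma cell line. Per the labels, the cells were grown with 10% serum, kept without serum for 72 h and stimulated for 30 min with 50 ng/ml PDGF-BB, a dimer of the platelet-derived growth factor B chain. LY294002, an inhibitor of phosphoinositide 3-kinase (PI3K), and U0126, an inhibitor of the kinase MEK that activates ERK, were added 60 min before PDGF. The groups follow the labels: PDGF alone (5 arrays), LY294002 with PDGF (2 arrays), U0126 with PDGF (2 arrays) and both inhibitors with PDGF (2 arrays). The second channel of every array was RNA of untreated serum-deprived cells. No array carried an inhibitor without PDGF. Nothing in the labels says whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

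The deposited values are taken as log2 ratios of the treated sample over the untreated reference. They lie near 0 on both sides and reach about 7, which excludes log10 on a 16-bit scanner, but base e is not excluded, and log2 units would then be 1.44 times larger. The direction treated over untreated is likely rather than stated: it rests on the series title and on the long positive tail of all 11 arrays. The dyes, any dye swap, the labelling method, the authors' normalization, and the filter that left spots empty are not given in the sources used here. The tables used here give ratios without signals, so dim spots were not left out.

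The arrays lie in 2 deposited tables, 1 per array platform. Table A holds PDGF replicates 1 to 4, LY294002 replicate 1 and U0126 replicate 1. Table B holds PDGF replicate 5, LY294002 replicate 2, U0126 replicate 2 and both arrays with the inhibitor pair. Each table lists 18564 spots, of which 48.1% to 62.3% had a value on an array. In table A, 10901 spots carried a single gene symbol, 137 several and 7526 none, and 236 of the single symbols were not those of a human gene. In table B the counts were 11666, 391, 6507 and 14. Only spots with a single human symbol were used. They gave 7279 genes with a value on any array and 3241 genes measured on all 11. Coordinates of the spots were not used here.

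Each array was centred on the median of its log2 ratios (medians of the deposited values ran from −0.319 to 0.085), and the spots of a gene were averaged per array. Models were fitted in R 4.3.3 with limma 3.58.1, on all 11 arrays at once, with the 4 groups and the table as terms, and variances were moderated across genes (prior variance 0.0136, 3.07 prior and 6 residual degrees of freedom). PDGF was tested as its mean against 0, which leaves out the spread of the untreated cells themselves. Inhibitor groups were tested against PDGF, against each other and against 0. A gene needed at least 3 PDGF arrays and both arrays of an inhibitor group. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided. For genes called higher with PDGF, the inhibitor comparisons were also adjusted over that list alone. Python 3.11.15 read the tables and drew the plots (matplotlib 3.10.9).

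On simulated data with 200 changed genes and the missing values of the real arrays, the PDGF test recovered 96% of changes of 0.5 (log2), with 5.8% of its calls false. For a change of 0.5 the LY294002 test recovered 68%, the U0126 test 64% and the test of both inhibitors 42%. For a change of 1 these were 94%, 96% and 84%, and 4.8%, 3.8% and 5.4% of their calls were false. The adjusted threshold is stricter when fewer genes change. On the real arrays these 3 tests called 51, 35 and 64 genes, so the recovery there may be lower than simulated.

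Named genes followed a rule set before the data were examined, as were the comparisons, the alternative settings and the gene lists. Per comparison with PDGF, the rule took up to 12 called genes per direction with the largest change that moved the same way on every array, and up to 4 members per list with the smallest p. FOS, EGR1, JUNB, MYC, DUSP1, DUSP6 and NR4A1 were always named. Genes named outside this rule are marked as chosen after their values were seen. Exceptions without a mark are list members named because they were called, CCN2 beside the BRAP spots and the targets set beside CYP1B1. The 19 lists were immediate-early transcription factors, other growth-factor-inducible immediate-early genes, ERK feedback regulators, secreted growth factors and cytokines, cytoskeletal targets of serum response factor, FOXO-activated genes, NF-kB targets, CREB targets, sterol synthesis genes, integrated stress response genes, heat shock genes, p53 targets, S-phase and mitosis genes, glycolysis and hypoxia genes, components of the PDGF receptor, PI3K and ERK pathways, ribosomal proteins, and markers of blood cells, epithelial cells, and glia and neurons. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 76 tests of list and comparison, and again with camera at an estimated correlation and with fry.

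Alternatives were no centring, equal spread of the arrays, quantile normalization, stricter and looser filters on missing values, leaving the table out of the model, each table alone, medians over spots, single spots, robust variances, other thresholds, fits on fewer groups, a replicate block, leaving out each array in turn, and choosing induced genes on other PDGF arrays than those they were compared with. Chosen after seeing the data were the use of 1 accession per gene, a fit of the blocked arrays without the block, and alternatives for the inhibitor groups against the untreated reference. Counting other splits of the samples was not applicable, since PDGF alone has at least 3 arrays.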

Results

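The series asked which genes that PDGF induces in a human glioblastoma cell line depend on the PI3K and the MEK/ERK pathways. Expression was recorded as log2 ratios to untreated serum-deprived cells on 5 arrays with PDGF, 2 with LY294002 and PDGF, 2 with U0126 and PDGF and 2 with both inhibitors and PDGF. Between 8937 and 11560 spots per array had a value. The number of arrays limits the precision, above all for the inhibitor groups. Across spots, which are not independent, Pearson's r between PDGF arrays of table A lay between 0.48 and 0.65 and Spearman's rho between −0.15 and 0.34. For PDGF replicate 4 and LY294002 replicate 1, r was 0.60.

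PDGF for 30 min raised immediate-early genes, which growth factors switch on without new protein synthesis. Among the named genes tested, the highest ratios were those of DUSP1, a phosphatase of MAP kinases (mean log2 ratio 5.13 ± 0.63, SD, n = 5), and ZFP36, a protein that destabilizes messenger RNA (4.59 ± 0.36, n = 5). The orphan nuclear receptor NR4A2 (4.19 ± 0.26, n = 5), the zinc-finger transcription factor EGR3 (4.16 ± 0.41, n = 5) and the AP-1 subunit JUNB (3.84 ± 0.31, n = 5) followed in order of fitted change. ATF3, CCN1 and TRIB1 were also among the 12 largest, with fitted changes of 3.69, 3.09 and 2.89, as were FOSB (3.91 ± 0.33, n = 3) and IER2 (3.42 ± 0.31, n = 5). Of 5514 genes tested against untreated cells, 136 were higher and 3 were lower. The lower ones were the potassium channel subunit KCNV1 (−0.35 ± 0.15, n = 5), the RNA export factor RAE1 (−0.23 ± 0.09, n = 5) and the collagen chain COL3A1 (−0.21 ± 0.05, n = 5).

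Of the reference genes for growth factor responses, MYC (1.18 ± 0.30, n = 5), DUSP6 (1.63 ± 0.49, n = 5) and EGR1 (1.30 ± 0.56, n = 5) were past the threshold, as were DUSP1 and JUNB. NR4A1 was past it too (3.42 ± 1.89, n = 5, adjusted p = 0.0281), but its spots disagreed: those of 1 accession lay between 4.57 and 6.75 with PDGF, those of the other between −0.60 and 0.17. FOS carried a symbol in table B alone and was not tested. Its log2 ratio was 6.37 on the PDGF array of that table. The spots named BRAP (3.22 ± 0.28, n = 5) were also among the 12 largest, and their values lay close to those of the strongest spots of CCN2, a secreted matricellular protein.

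Among the fixed lists, 20 of 26 immediate-early transcription factors rose with PDGF (24 adjusted over the list alone), with a median change of 1.32 and a list adjusted p of 4.83e-48. Of 23 other immediate-early genes 20 rose (22 adjusted over the list alone), among them MCL1, a survival protein of the BCL2 family (1.47 ± SE 0.05), and the kinase SGK1 (2.43 ± SE 0.12). Of 16 ERK feedback regulators 6 rose, the phosphatases DUSP1, DUSP4, DUSP5 and DUSP6 with IER3 and PHLDA1 (8 adjusted over the list alone). Of 28 secreted factors 12 rose (18 adjusted over the list alone, and 1 fell), including the chemokine CXCL8 (1.90 ± SE 0.07), the protease PLAU (1.55 ± SE 0.07) and tissue factor, F3 (1.07 ± SE 0.08). Of 25 NF-kB targets 10 rose (12 adjusted over the list alone), and of 20 CREB targets 9 rose (14 adjusted over the list alone). With an estimated correlation these 6 lists kept adjusted p between 0.0033 and 0.0132. They share members and are not independent. Of the NF-kB targets that rose, only CD83, CXCL10 and IRF1 were in no other of these lists. Of the CREB targets that rose, this held only for BDNF and PER1.

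Other lists had fewer members past the threshold over all genes. Of 16 integrated stress response genes 3 rose, ATF3, CEBPB and DDIT3 (6 adjusted over the list alone; adjusted p = 0.0359 with an estimated correlation). Of 14 heat shock genes 2 rose, the cochaperones DNAJB1 and DNAJB4 (3 adjusted over the list alone; adjusted p = 0.0387 with an estimated correlation); the list median of 0.05 was −0.02 without centring. Of 19 cytoskeletal targets of serum response factor 2 rose, ACTG1 and SRF itself (8 adjusted over the list alone), and the list call was lost (adjusted p = 0.158 with an estimated correlation). Of 15 p53 targets 4 rose, CDKN1A, GADD45A, PLK2 and PLK3, all growth-factor-inducible too (6 adjusted over the list alone). The p53 list call was lost (adjusted p = 0.184 with an estimated correlation), and its median of 0.01 was −0.06 without centring and −0.00 with equal spread. Leaving out centring shifts all genes of an array alike, so it hardly moves the heat shock and p53 lists against other genes. None of 17 ribosomal protein genes passed the test, and the list was called lower (adjusted p = 0.00582, and adjusted p = 0.512 with an estimated correlation). No list call was made for FOXO-activated genes (2 of 17 rose, IRS2 and GADD45A), sterol synthesis (1 of 14, IDI1), glycolysis and hypoxia (1 of 18, ADM), S-phase and mitosis (0 of 32) or pathway components (0 of 24). None of the 14 blood, 10 epithelial and 10 glial or neuronal markers passed.

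In table A 139 of the 139 called genes had the direction of the joint fit, and in table B 129 of the 129 measured there, which a call nearly requires. Without PDGF replicate 5 the number called was 88, and without centring the split was 109 higher and 24 lower.

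Among the genes that fell with LY294002 were a transporter, chemokines and other secreted or inflammatory genes. The transporter SLCO1A2 had a mean of −2.10 ± 0.19 (SD, n = 2) against 1.25 ± 0.52 (n = 5) with PDGF, a change of −3.29 (SE 0.32, adjusted p = 0.00131). The chemokine CCL8 changed by −2.46 (SE 0.16, adjusted p = 0.00015) and TNFAIP3, an inhibitor of NF-kB signalling, by −2.45 (SE 0.28, adjusted p = 0.00283). CXCL8 changed by −2.06 (SE 0.12), PLAU by −1.56 (SE 0.13), the G protein regulator RGS2 by −1.54 (SE 0.17), F3 by −1.49 (SE 0.14) and IL6 by −1.34 (SE 0.18). Both LY294002 arrays lay below the PDGF mean for each, which the rule for naming the largest changes required. SRF, the transcription factor serum response factor, fell from 1.15 ± 0.11 (n = 5) to 0.02 ± 0.09 (n = 2).

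In contrast to these genes, several immediate-early genes stayed high on both LY294002 arrays and were not past the threshold. ZFP36 was at 4.65 ± 0.94 (n = 2), TRIB1 at 2.71 ± 0.70 (n = 2), EGR1 at 1.75 ± 0.05 (n = 2) and DUSP6 at 1.36 ± 0.05 (n = 2). The fitted changes with LY294002 were −0.69 for DUSP1, −0.36 for DUSP6 and 0.29 for EGR1. MYC did not stay high: it went from 1.18 ± 0.30 (n = 5) to 0.36 ± 0.00 (n = 2), a change of −0.81 that was not past the threshold over all genes (adjusted p = 0.128) but was called lowered over the induced genes alone (adjusted p = 0.0069). For JUNB the change was −0.14, and it was 0.26 with equal spread and 0.46 with quantile normalization. For NR4A1 it was −0.14, and 0.62 and 0.51 with the same scalings; DUSP1 turned to 0.27 with quantile normalization and EGR1 to −0.34 in table B alone.

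Genes higher with LY294002 were led by histone genes: H2BC8 (1.65, SE 0.13), H2AC8 (1.61, SE 0.14), H3C4 (1.17, SE 0.11), H2BC12 (1.14, SE 0.10), H2AC17 (1.03, SE 0.14), H2AJ (0.74, SE 0.13) and H2AX (0.55, SE 0.09). The remaining 6 were CHRFAM7A (1.54, SE 0.17), a partial duplicate of a nicotinic receptor gene, AAMP (0.80, SE 0.11), CLK1 (0.73, SE 0.14), a kinase of splicing factors, the cochaperone DNAJB1 (0.72, SE 0.11), ATF4 (0.71, SE 0.08), the transcription factor of the integrated stress response, and the cell cycle inhibitor CDKN1C (0.41, SE 0.08). CDKN1C lay outside the rule for named genes and was chosen after its value was seen. Of 4761 genes tested, 13 were higher and 38 lower than with PDGF alone.

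By list, 5 of 21 secreted factors fell with LY294002 (10 adjusted over the list alone; list adjusted p = 6.59e-11, and adjusted p = 0.0033 with an estimated correlation). Of 21 NF-kB targets 5 fell, CXCL10, CXCL8, IL6, IRF1 and TNFAIP3 (8 fell and 1 rose adjusted over the list alone; adjusted p = 0.0258 with an estimated correlation). Of 17 CREB targets 1 fell, RGS2 (6 adjusted over the list alone; adjusted p = 0.0301 with an estimated correlation). Other list calls were lost with an estimated correlation: immediate-early transcription factors (1 of 24 fell, SRF, and 5 fell and 3 rose adjusted over the list alone, adjusted p = 0.244 with an estimated correlation), other immediate-early genes (4 of 22 fell, MCL1, PLK2, RGS2 and TNFAIP3, and 7 fell and 1 rose over the list alone, adjusted p = 0.0968 so estimated) and ERK feedback regulators (2 of 15 fell, DUSP4 and DUSP5, and 6 over the list alone, adjusted p = 0.0985 so estimated). The same held for serum response factor targets (1 of 19 fell, SRF, and 2 fell and 1 rose over the list alone, adjusted p = 0.251 so estimated) and S-phase genes (0 of 31, called lower, adjusted p = 0.711 so estimated). Ribosomal proteins (0 of 14, 1 higher over the list alone, called higher, adjusted p = 0.149 so estimated) and FOXO-activated genes (0 of 17, called higher, adjusted p = 0.251 so estimated) did so too. The FOXO list median of 0.12 was −0.06 without centring, 0.10 above the median of all genes. On genes measured on all arrays the preset correlation lost the S-phase call too (adjusted p = 0.187). Fry kept the calls for other immediate-early genes (adjusted p = 0.00994), ERK feedback regulators (adjusted p = 0.0294) and ribosomal proteins (adjusted p = 0.0294). Not called were integrated stress response genes (1 of 15 rose, ATF4), heat shock genes (1 of 11 rose, DNAJB1), p53 targets (1 of 15 fell, PLK2), sterol synthesis (0 of 13), glycolysis and hypoxia (0 of 16), pathway components (0 of 24) and the blood (0 of 9), epithelial (0 of 8) and glial or neuronal markers (0 of 9).

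All 51 called genes had the same direction in each table, which a call nearly requires, and with 1 LY294002 array per table neither table alone gave a call. The number called was 22 without LY294002 replicate 1, where the balance turned to 14 higher and 8 lower, 18 without LY294002 replicate 2 (6 and 12) and 20 without PDGF replicate 5 (5 and 15), and without centring, which put the median of all genes at −0.16, the split was 8 higher and 87 lower, against 19 and 27 with equal spread.

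**Figure D1:**
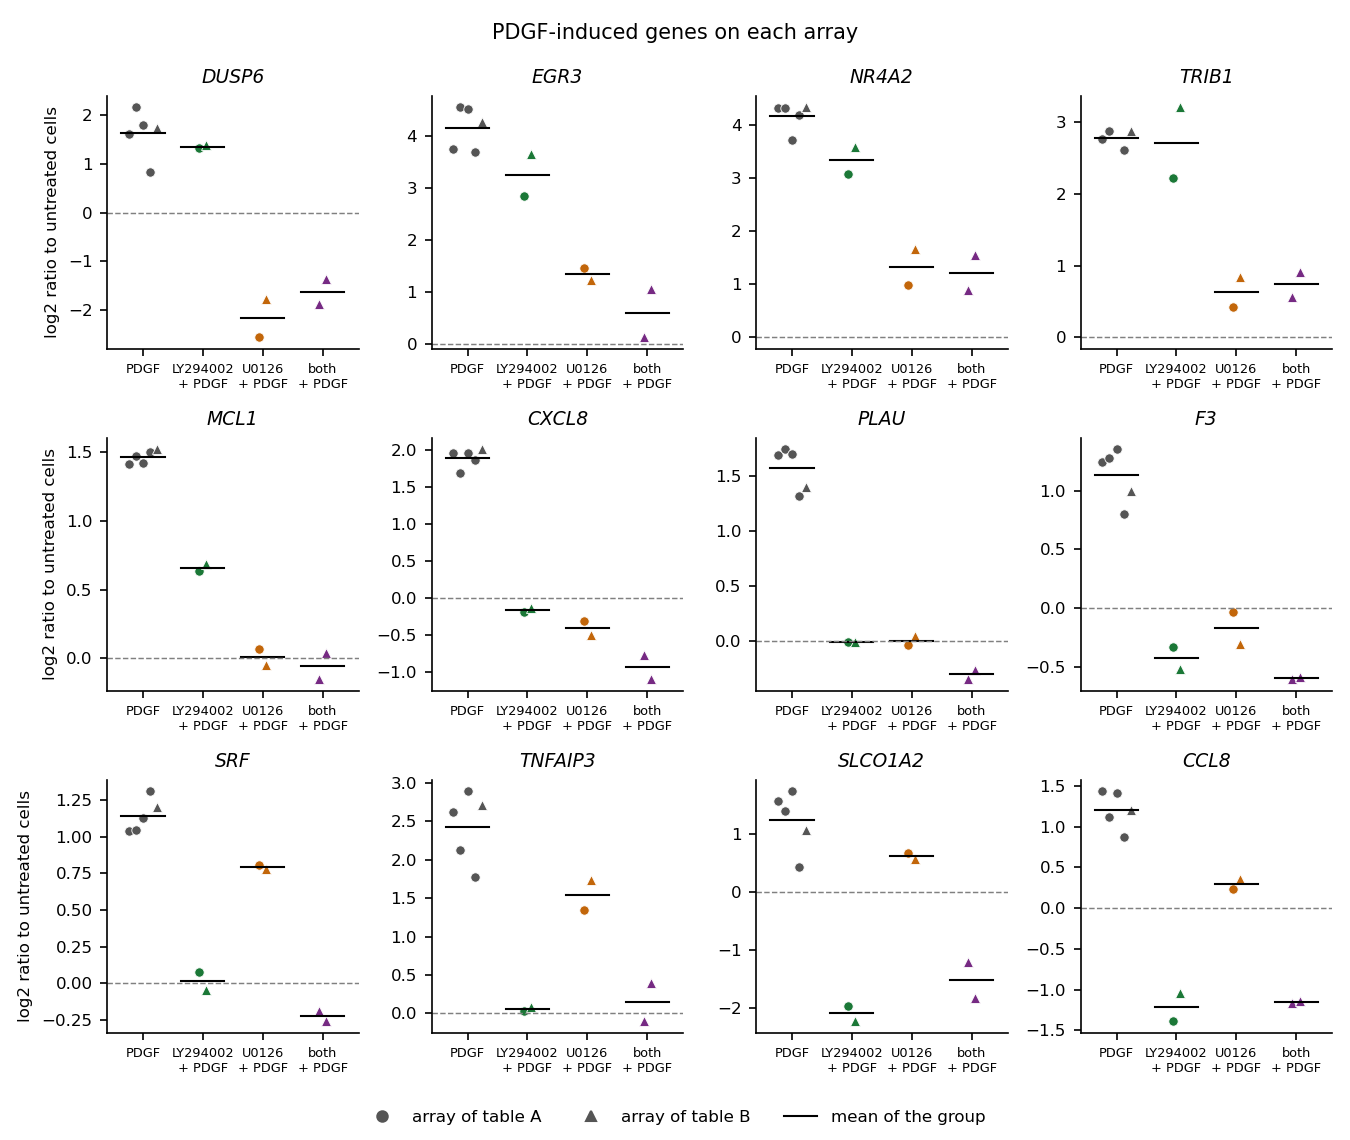
Log2 ratio to untreated cells (y axis) of 12 PDGF-induced genes on each of the 11 arrays, by group (x axis); points are arrays, circles those of table A and triangles those of table B, black lines are group means and the dashed line marks untreated cells. DUSP6 lies at 1.36 ± 0.05 (SD, n = 2) with LY294002 and at −2.17 ± 0.56 (n = 2) with U0126, while SLCO1A2 lies at −2.10 ± 0.19 and 0.63 ± 0.07.

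Among the genes that fell with U0126 were immediate-early transcription factors and 3 phosphatases of the ERK feedback list, DUSP4, DUSP5 and DUSP6. DUSP6, a phosphatase of ERK, fell furthest, from 1.63 ± 0.49 (n = 5) to −2.17 ± 0.56 (n = 2), a change of −3.89 (SE 0.33, adjusted p = 0.000415). NR4A2 changed by −2.98 (SE 0.22, adjusted p = 0.000191), EGR3 by −2.87 (SE 0.34, adjusted p = 0.00426) and IER2 by −2.62 (SE 0.40, adjusted p = 0.0184). CXCL8 changed by −2.30 (SE 0.12), the pseudokinase TRIB1 by −2.26 (SE 0.19), DUSP5 by −2.03 (SE 0.12), SGK1 by −1.98 (SE 0.17), JUNB by −1.84 (SE 0.30) and MCL1 by −1.46 (SE 0.08). MYC (−1.25, SE 0.20) and EGR1 (−1.44, SE 0.26, adjusted p = 0.0492) fell as well.

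DUSP1 (−1.27, SE 0.40, adjusted p = 0.465) and NR4A1 (−0.88, SE 1.07) were not past the threshold with U0126. Both turned positive with equal spread (0.86 and 0.71) and with quantile normalization (0.68 and 0.40). Equal spread enlarges all ratios on the U0126 arrays relative to PDGF, since their spread was the smallest. Higher with U0126 were 3 genes: the cytochrome CYP1B1 (1.13, SE 0.07), the cell cycle inhibitor CDKN1B (0.99, SE 0.13), also known as p27, and the homeobox gene IRX5 (0.68, SE 0.11). Of 4426 genes tested, 32 were lower than with PDGF alone.

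By list, 9 of 22 immediate-early transcription factors fell with U0126 (14 fell and 1 rose adjusted over the list alone), with a median change of −0.85 and a list adjusted p of 3.84e-22. Of 20 other immediate-early genes 6 fell, ARC, MCL1, PLK2, RND3, SGK1 and TRIB1 (15 adjusted over the list alone). Of 14 ERK feedback regulators 3 fell, DUSP4, DUSP5 and DUSP6 (8 adjusted over the list alone). Of 21 secreted factors 3 fell, CXCL8, F3 and PLAU, of 22 NF-kB targets 2, CXCL8 and IRF1, and of 15 CREB targets 3, ATF3, NR4A2 and SGK1 (6 in each list adjusted over the list alone). With an estimated correlation these lists had adjusted p between 0.0033 and 0.0134. Calls were lost for integrated stress response genes (2 of 14 fell, ATF3 and CEBPB, and 3 over the list alone, adjusted p = 0.149 with an estimated correlation, median −0.06 and 0.04 without centring), heat shock genes (1 of 9 fell, DNAJB1, and 2 over the list alone, adjusted p = 0.0602 so estimated) and serum response factor targets (0 of 18, also over the list alone, adjusted p = 0.623 so estimated, median −0.09 and 0.01 without centring). Without centring the median of all genes rose too, and the medians of the stress response list and of serum response factor targets stayed below it. For serum response factor targets the preset correlation lost the call too on genes measured on all arrays (adjusted p = 0.068). Not called were FOXO-activated genes (1 of 16 rose, CDKN1B), p53 targets (1 of 14 fell, PLK2), sterol synthesis (0 of 13), S-phase and mitosis (0 of 29), glycolysis and hypoxia (0 of 15), pathway components (0 of 23), ribosomal proteins (0 of 15) and the blood (0 of 6), epithelial (0 of 9) and glial or neuronal markers (0 of 7).

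Of the 35 called genes, 35 of 35 in table A and 33 of 33 measured in table B had the same direction, which a call nearly requires, while table A alone gave 6 calls and table B alone 0. The number was 13 without either U0126 replicate 1 or U0126 replicate 2, 21 without PDGF replicate 5 and 22 without either array of both inhibitors, and equal spread gave 8 higher and 18 lower, quantile normalization 11 and 39, and no centring 6 and 26 with the median of all genes at 0.10.

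With both inhibitors, 25 of the 38 genes that fell with LY294002 fell too, as did 28 of 31 tested that fell with U0126. These comparisons share the PDGF arrays. Simulated unchanged groups shared 0 genes, but they had a median of 0 induced genes lowered. They cannot show what the shared arrays add among changed genes. With separate PDGF arrays the shared numbers were 12.5 and 14 (medians). Each comparison then had fewer PDGF arrays, which by itself limits the calls. EGR3 changed by −3.74 against PDGF (SE 0.41, adjusted p = 0.00153), DUSP6 by −3.50 (SE 0.39), NR4A2 by −3.30 (SE 0.26), CXCL8 by −2.84 (SE 0.14), DUSP5 by −2.70 (SE 0.14), SGK1 by −2.69 (SE 0.23) and the transcription factor KLF10 by −2.66 (SE 0.22). SLCO1A2 (−2.61, SE 0.39), TNFAIP3 (−2.51, SE 0.33) and CCL8 (−2.46, SE 0.18) fell with them, as did MYC (−1.85, SE 0.23), which reached −0.69 ± 0.15 (SD, n = 2). JUNB (−1.46, SE 0.35, adjusted p = 0.137; 0.49 with quantile normalization), EGR1 (−1.26, SE 0.31, adjusted p = 0.146), DUSP1 (−1.71, SE 0.48, adjusted p = 0.238; 0.43 with quantile normalization) and NR4A1 (−1.53, SE 1.27) were not past the threshold. The genes that were higher were 6 histone genes, led by H2BC8 (2.11, SE 0.15) and H2AC8 (2.01, SE 0.17), and CHRFAM7A (1.70, SE 0.20). Of 4816 genes tested, 7 were higher and 57 lower, and 13 and 42 with quantile normalization.

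By list, 11 of 25 immediate-early transcription factors fell with both inhibitors (18 fell and 1 rose adjusted over the list alone), 9 of 21 other immediate-early genes (17) and 5 of 14 ERK feedback regulators (8). Of 25 secreted factors 4 fell (11 adjusted over the list alone), of 22 NF-kB targets 5 (8) and of 19 CREB targets 4 (9). These 6 lists had adjusted p between 0.0033 and 0.0132 with an estimated correlation. Calls were lost for serum response factor targets (1 of 19 fell, SRF, and 2 over the list alone, adjusted p = 0.18 with an estimated correlation), heat shock genes (1 of 12 fell, DNAJB4, and 3 over the list alone, adjusted p = 0.0848 so estimated) and ribosomal proteins (0 of 15, called higher, adjusted p = 0.184 so estimated). Not called were integrated stress response genes (2 of 16 fell, ATF3 and CEBPB), p53 targets (1 of 14 fell, PLK2), FOXO-activated genes (0 of 17), sterol synthesis (0 of 14), S-phase and mitosis (0 of 31), glycolysis and hypoxia (0 of 17), pathway components (0 of 23) and the blood (0 of 14), epithelial (0 of 9) and glial or neuronal markers (0 of 9).

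Both arrays of this group lie in table B with 1 PDGF array, where 63 of the 63 genes measured had the same direction, which a call nearly requires. The number called was 31 without PDGF replicate 5, and 30 and 32 without replicate 1 or 2 of both inhibitors, and 107 without the table in the model.

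The inhibitors were also compared with each other. DUSP6 was 3.53 higher with LY294002 than with U0126 (SE 0.38, adjusted p = 0.00325), TRIB1 2.08 (SE 0.21), NR4A2 2.01 (SE 0.26), EGR1 1.72 (SE 0.30), DUSP5 1.33 (SE 0.14) and SGK1 1.29 (SE 0.17). SLCO1A2 was lower with LY294002 by −2.73 (SE 0.37, adjusted p = 0.0107), CCL8 by −1.51 (SE 0.18), CYP1B1 by −1.19 (SE 0.08) and SRF by −0.78 (SE 0.11). By list, camera at the preset correlation called immediate-early transcription factors (adjusted p = 4.93e-08 over the lists of this comparison) higher with LY294002. It also called other immediate-early genes (1.02e-10) and ERK feedback regulators (6.46e-05) higher, among other lists. Fry gave each of these 3 an adjusted p of 0.0157. With an estimated correlation no list passed (lowest adjusted p = 0.153), so a difference by list depends on the test. Of 4311 genes, 34 were higher and 13 lower with LY294002. Without centring the split was 24 and 93, with the median of all genes at −0.27, and with equal spread 36 and 39. The number called was 6 without LY294002 replicate 2, 8 without U0126 replicate 1 and 1 without U0126 replicate 2.

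Adding U0126 to LY294002 lowered 12 of 4505 genes and raised none with limma (187 at an unadjusted p under 0.05). Among them were DUSP6 (−3.14, SE 0.40), EGR3 (−2.76, SE 0.42), KLF10 (−2.42, SE 0.22), NR4A2 (−2.33, SE 0.27) and DNAJB1 (−1.22, SE 0.13). Adding LY294002 to U0126 lowered 6 of 4176 genes, including CCL8 (−1.51, SE 0.19), IRX5 (−1.36, SE 0.13), CYP1B1 (−1.29, SE 0.09) and SRF (−1.01, SE 0.11). It raised 5, the histone genes H2BC8, H2AC8, H2AC17, H3C4 and H2BC12, by 1.31 to 2.19. The count of 12 was 0 without LY294002 replicate 2, 1 and 7 without replicate 1 or 2 of both inhibitors, and 4 with equal spread. The count of 11 was 7 without U0126 replicate 1, 2 without U0126 replicate 2 and 7 without replicate 2 of both inhibitors. Its split of 5 higher and 6 lower was 6 and 20 without centring, with the median of all genes at −0.17, and 10 and 20 with equal spread.

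Over the 136 genes that PDGF raised, LY294002 lowered 52 of 122 tested and raised 8 (30 and 2 adjusted over all genes), with a median change of −0.32. U0126 lowered 78 of 119 and raised 1 (32 and 0), with a median of −0.46, and both inhibitors lowered 102 of 125 and raised 2 (48 and 0), with a median of −0.78. The share of the PDGF response that remained was taken per gene as the log2 ratio with inhibitor over that with PDGF. Its median was 64.6% with LY294002, 32.9% with U0126 and 1.7% with both. This share was computed on centred values alone and is negative for genes below untreated cells. Without arrays of an inhibitor alone, a fall of basal expression counts in it as lost response. Of 117 genes tested with each inhibitor, 34 were lowered by each, CXCL8, PLAU, F3, MCL1, NR4A2 and EGR3 among them, against 34.7 for independent sets. A call with LY294002 alone was made for 18, such as SLCO1A2, CCN1 and IL6, and with U0126 alone for 44, such as DUSP6, TRIB1 and IER2. DUSP1 was among these 44, although its change with U0126 turned to 0.86 with equal spread and to 0.68 with quantile normalization. The direct test over these 117 genes placed 21 lower with LY294002 and 44 lower with U0126. Both inhibitors together were lower than LY294002 for 53 of 119 genes and lower than U0126 for 24 of 116, and higher than U0126 for 1.

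The inhibitor comparisons share the PDGF arrays on which the 136 genes were chosen. Simulated groups with no change gave at most 4, 3 and 5 lowered genes, although they called a median of 186.5 induced genes, above the 136 observed. Their shared count of at most 1 follows from those few calls and does not show what the shared arrays add among lowered genes. Across all genes, which are not independent, r between the LY294002 and U0126 changes was 0.40, where simulated groups gave 0.36 (at most 0.42) and separate PDGF arrays 0.22. The size of the difference between the inhibitors depended on the scaling. Without centring LY294002 lowered 56 of 95 genes (median −0.55) and U0126 50 of 91 (median −0.53), so the order turned. In those values the median of all genes itself lay below PDGF with LY294002 and above it with U0126. This offset adds to the LY294002 count, so the turn does not show that the order among induced genes changed. With equal spread the counts were 42 of 116 (median −0.25) and 50 of 111 (−0.31), and with quantile normalization 45 of 117 (−0.24) and 50 of 112 (−0.27). The order of the main fit stayed with both of these scalings. U0126 lowered 48 of 113 without U0126 replicate 1, and both inhibitors 66 of 78 without PDGF replicate 5.

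**Figure D2:**
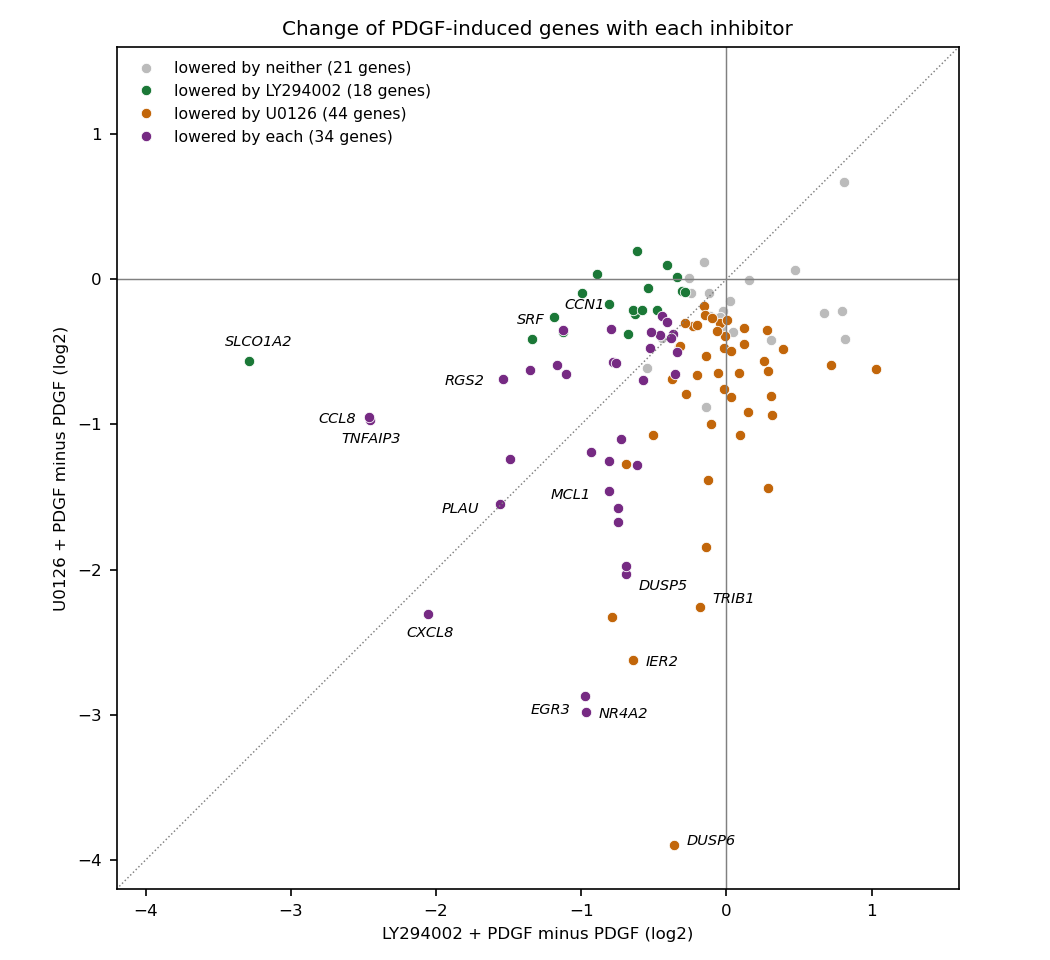
Change against PDGF alone with LY294002 (x axis, log2) and with U0126 (y axis, log2) for the 117 PDGF-induced genes tested with each; each point is a gene, colours give the call adjusted over the induced genes and the dotted line marks equal change. DUSP6, TRIB1 and IER2 lie low on the y axis near 0 to −0.64 on the x axis, SLCO1A2 lies at −3.29 on the x axis, and 34 genes were lowered by each.

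Against untreated cells, 81 genes were higher and 31 lower of 4860 with LY294002, 33 and 3 of 4485 with U0126, and 25 and 13 of 5870 with both inhibitors. Of the induced genes, 72, 51 and 21 were still above untreated cells, adjusted over the list alone, and 11, 4 and 18 were below them. Those below with U0126 were CXCL8, DUSP4, DUSP6 and FILIP1L; those with LY294002 included CCL8, SLCO1A2, F3 and HEG1. MYC, KLF10, RGS2 and IRF1 were below with both inhibitors. FILIP1L was chosen after its value was seen. Without centring the splits were 65 higher and 589 lower with LY294002 and 24 and 59 with both inhibitors, with the medians of all genes at −0.25 and −0.15. The counts were 64 without LY294002 replicate 1 and 36 without replicate 2, 4 without U0126 replicate 1 and 2 without replicate 2, and 11 and 4 without replicate 1 or 2 of both inhibitors.

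The histone genes, grouped after their values were seen, were examined as a set. With LY294002 7 of 9 were higher (8 adjusted over the list alone, median change 1.03), with both inhibitors 6 of 9 (median 1.35), and with U0126 0 of 7 (median −0.08, and 0.01 without centring). The direct test placed 6 of 7 above U0126 with LY294002. H2BC8 had a mean of −0.04 ± 0.10 (SD, n = 5) with PDGF, 1.67 ± 0.42 (n = 2) with LY294002, −0.06 ± 0.00 (n = 2) with U0126 and 2.22 ± 0.06 (n = 2) with both. Without centring 5 of the 9 were called with LY294002. H1-10 did not follow (0.03, SE 0.18), and H3C10 did not pass the test (0.29, SE 0.10).

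**Figure D3:**
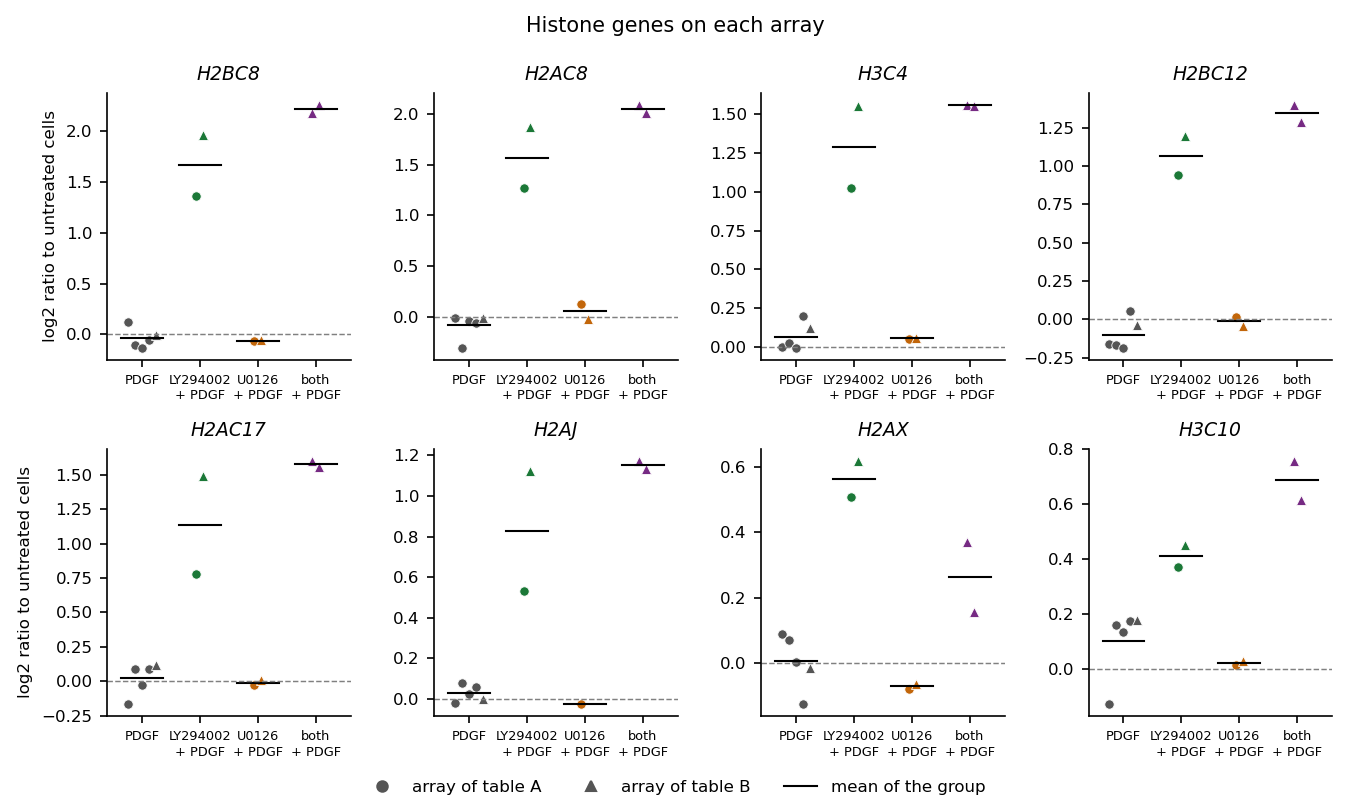
Log2 ratio to untreated cells (y axis) of 8 histone genes on each of the 11 arrays, by group (x axis); points are arrays, circles those of table A and triangles those of table B, black lines are group means. H2BC8 lies near 0 on the PDGF and U0126 arrays and at 1.67 ± 0.42 (SD, n = 2) with LY294002.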

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

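The tests on histone genes, on the induced genes and on the BRAP spot below were chosen after the results were seen.

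The histone genes were higher with LY294002 and not with U0126. Centring is not the source, since their median change in the uncentred values was 0.852 (SE over genes 0.185). The 7 called genes were higher in each table, but a call in the joint fit nearly requires that, so this count cannot decide on a difference between the array tables. The sizes argue against it for these genes. LY294002 minus PDGF was 0.497 to 1.411 within table A and 0.634 to 1.975 within table B, with 1 LY294002 array in each. Their single PDGF arrays lay between −0.306 and 0.199. For the uncalled H3C10 the changes were 0.285 and 0.273, and for H1-10 0.177 and −0.21. More cells in S phase would raise other S-phase genes too. The list of S-phase and mitosis genes had a median change of −0.033 (SD over genes 0.142), and 0 of 31 were called higher, also over the list alone. It mixes genes of both phases, so its median does not give the S-phase members alone. Reading of 1 transcript by several spots would keep to 1 subfamily, but 3 subfamilies had called genes, although genes within a subfamily cannot be separated. An effect of LY294002, through PI3K or other targets, or a change in how histone transcripts enter the labelled sample may explain it. These cannot be told apart here. Whether PDGF is needed is open too, since no array had an inhibitor alone.

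The lowering of PDGF-induced genes was tested against the choice of genes on shared PDGF arrays, where simulated unchanged groups gave at most 5 lowered genes against 52 or more observed. A smaller spread of ratios on the inhibitor arrays would scale all genes by 1 factor, but squared deviations from such a factor were at least 8.21 times the squared errors. Such a factor alone therefore cannot account for all these genes. A part played by the spread is not excluded. U0126 lowered fewer induced genes with equal spread, but this cannot decide on it. The U0126 arrays had the smallest spread (SD from the median absolute deviation 0.092 and 0.113, against 0.135 to 0.202 with PDGF). Equal spread therefore enlarges their ratios relative to PDGF by construction. Whether loss of ERK or PI3K signalling or other targets of the compounds lowered these genes was not tested, since no array measures the activity of either pathway.

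The spots named BRAP, high with PDGF, may report CCN2: their root mean square difference from the strongest CCN2 spots was 0.159 over 9 arrays, the smallest of 5829 compared, with 0.484 to the next, ATF3, and a median of 0.438 for spot pairs of the same gene. The sequence on the spot was not used here.

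Among 41 named genes tested for an array lying apart within PDGF, 5 had one, and some are expected by chance at about 1 in 20 groups. NR4A2 was 3.732 on PDGF replicate 3, where the others lay between 4.20 and 4.34. JUNB was 3.314 on PDGF replicate 3, where the others lay between 3.84 and 4.05. NR4A1 was 6.752 on PDGF replicate 4, where the others lay between 2.23 and 3.03 and the low spot of the gene has no value. CCN1 was 3.645 on PDGF replicate 4, where the others lay between 2.83 and 2.98. IRS2 was 0.527 on PDGF replicate 4, where the others lay between 0.96 and 1.14.

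Among spots without a usable human symbol, 34 of 2826 in table A passed the threshold with PDGF, the highest at 6.50, and 19 were higher and 1 lower of 2071 in table B, and they enter no gene result. FOS was at 6.366 with PDGF in table B, at 7.18 with LY294002, at 5.48 with U0126 and at 5.10 and 6.01 with both inhibitors, on single arrays.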

How the results depend on the processing

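Counts of called genes depended on the setting, and of 3526 values of named genes under other settings 2990 kept their direction and their side of the threshold, 507 kept the direction but were no longer past it, 10 kept the direction and were newly past it, and 19 turned direction. None of these 19 was past the threshold over all genes, but DUSP1 with U0126 and JUNB and DUSP1 with both inhibitors were called lowered when adjusted over the induced genes alone. Unless construction shows it (fewer arrays or genes), the cause was not tested. A filter on dim spots was not run, since the tables used here give ratios alone.

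Without centring, LY294002 against PDGF gave 95 called genes, LY294002 against U0126 117, both inhibitors against U0126 26, LY294002 against untreated cells 654 and both inhibitors against untreated cells 83, and U0126 lowered 50 of 91 induced genes. With equal spread, LY294002 against U0126 gave 75, both inhibitors against LY294002 4 and against U0126 30, U0126 against untreated cells 75, and U0126 lowered 50 of 111 induced genes. With quantile normalization U0126 lowered 50 of 112. Genes measured on all 11 arrays gave 7 for both inhibitors against LY294002. Without the table in the model, both inhibitors gave 107 against PDGF, 23 against LY294002, 22 against U0126 and 74 against untreated cells.

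Table A alone gave 85 for PDGF, 0 for LY294002 and 6 for U0126, and table B alone 70, 0 and 0. A lone array in a group is assumed there to vary like the other groups. Single spots gave 0 for LY294002 and 3 for U0126 in table A, and 80 for PDGF, 11 for LY294002 and 0 for U0126 in table B. A fold of at least 1.5 left 80 for PDGF. Fits on the groups of the comparison alone gave 72 for PDGF, 24 for LY294002, 21 for U0126 and 28 for both inhibitors. Choice of induced genes on other PDGF arrays, over 10 splits, left a median of 67 lowered by both inhibitors and a median of 92.5 tested. The median share lowered was 41.6% with LY294002, 67.8% with U0126 and 77.8% with both. In the main fit these shares were 42.6%, 65.5% and 81.6%. With an estimated correlation 23 of 39 list calls stayed. Fry called 33 of the 76 tests. With PDGF it kept serum response factor targets (adjusted p = 0.00309) and p53 targets (adjusted p = 0.00472). It also called blood cell markers (2 members, adjusted p = 0.0362). Other immediate-early genes, ERK feedback regulators and ribosomal proteins stayed with LY294002. Stress response and heat shock genes stayed with U0126, serum response factor targets and heat shock genes with both. Other lost calls were lost with fry too.

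A replicate block over 8 arrays gave 10 for LY294002 (1 higher, 9 lower), 25 for both inhibitors (0 and 25), 4 for both inhibitors against U0126 (0 and 4) and 55 of 60 induced genes lowered by both. With the block none of the 7 histone genes called with LY294002 passed, nor of the 6 called with both: for H2BC8, LY294002 + PDGF against PDGF gave 1.47 (adjusted p = 0.0877), and for H2BC12, LY294002 + PDGF against PDGF gave 1.15 (adjusted p = 0.0508). The same 8 arrays without the block gave 23 for LY294002 (5 and 18), 49 for both inhibitors against PDGF (5 and 44) and 19 for both inhibitors against LY294002. Differences between equally numbered arrays correlated across genes, which are not independent, at r of −0.03 to 0.25.

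Leaving out 1 array at a time gave these counts, where a lone array left in a group is assumed to vary like the other groups. PDGF: 88 without PDGF replicate 5 (at most 140, without replicate 1 or replicate 4). LY294002 against PDGF: 22 without LY294002 replicate 1, 18 without its replicate 2, 20 without PDGF replicate 5. Without PDGF replicate 4 the counts were highest: 65 for LY294002, 43 for U0126 and 76 for both inhibitors against PDGF, 61 for LY294002 against U0126, 17 for both inhibitors against LY294002, 102 induced genes lowered by both, and 136, 41 and 47 for LY294002, U0126 and both against untreated cells. U0126 against PDGF: 21 without PDGF replicate 5, 13 without U0126 replicate 1, 13 without its replicate 2, 22 without each array of both inhibitors. Both inhibitors against PDGF: 31 without PDGF replicate 5, 30 and 32 without replicates 1 and 2 of both inhibitors. LY294002 against U0126: 6 without LY294002 replicate 2, 8 and 1 without U0126 replicates 1 and 2. Both inhibitors against LY294002: 0 without LY294002 replicate 2, 1 and 7 without replicates 1 and 2 of both inhibitors. Both inhibitors against U0126: 7 and 2 without U0126 replicates 1 and 2, 7 without replicate 2 of both inhibitors. Induced genes lowered: 48 of 113 by U0126 without its replicate 1, 66 of 78 by both inhibitors without PDGF replicate 5. Against untreated cells: LY294002 64 and 36 without its replicates 1 and 2, U0126 4 and 2, both inhibitors 11 and 4.

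Reversed values with LY294002 against PDGF were JUNB 0.258 with equal spread, 0.456 with quantile normalization, 0.071 without the table, 0.672 in table B and 0.587 without LY294002 replicate 1. For NR4A1 they were 0.619 with equal spread, 0.507 with quantile normalization, 0.763 with the replicate block and 0.536 without PDGF replicate 4, for DUSP1 0.265 with quantile normalization, and for EGR1 −0.339 in table B and −0.109 without LY294002 replicate 1. At the other end of leaving out 1 array, EGR1 was 0.571 without PDGF replicate 5, JUNB −0.665 without LY294002 replicate 2, and for NR4A1, LY294002 + PDGF against PDGF gave −0.434 without PDGF replicate 3. For DUSP1, U0126 + PDGF against PDGF gave 0.858 with equal spread and 0.676 with quantile normalization. For NR4A1, U0126 + PDGF against PDGF gave 0.708 with equal spread, 0.402 with quantile normalization and 0.023 with the replicate block. With both inhibitors they were JUNB 0.485 and DUSP1 0.434 with quantile normalization.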

Other observations

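Some genes that were not past the threshold with PDGF were past it with an inhibitor. ATF4, the transcription factor of the integrated stress response, was at 0.05 ± 0.09 (SD, n = 5) with PDGF and at 0.81 ± 0.20 (n = 2) with LY294002, and CLK1, a kinase of splicing factors, went from −0.26 ± 0.16 (n = 5) to 0.47 ± 0.17 (n = 2). DNAJB1, a cochaperone that PDGF also raised (0.51, SE 0.06), was raised further by LY294002 (0.72, SE 0.11) and lowered by U0126 (−0.59, SE 0.11), and adding U0126 to LY294002 lowered it by −1.22 (SE 0.13). CDKN1B, a cell cycle inhibitor, was at 0.95 ± 0.01 (n = 2) with U0126 and 0.37 ± 0.09 (n = 2) with both inhibitors.

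CYP1B1, a cytochrome that the aryl hydrocarbon receptor induces, was at 1.06 ± 0.04 (n = 2) with U0126 but at −0.28 ± 0.09 (n = 2) with both inhibitors, a difference of −1.29 (SE 0.09, adjusted p = 0.000482). From general knowledge, U0126 can activate this receptor and LY294002 can block it, so the rise may come from the compound and not from loss of MEK activity. The test, written after CYP1B1 was seen and before its other targets were, gave a median change with U0126 of 0.172 (SE over genes 0.124) over only 2 measured targets, CYP1A1 (0.05, SE 0.12) and SLC7A5 (0.30, SE 0.17), so the explanations cannot be told apart. A MEK inhibitor of another structure, with CYP1A1 measured by PCR, would separate them.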
